A study of Sus scrofa with 19 samples.

How the data were processed

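RNA sequencing of pig brain was examined in 19 libraries from the frontal and the temporal cortex. All libraries came from brains subjected to 30 min of global cerebral ischemia, either with the liver made ischemic at the same time (brain-liver ischemia) or with the liver perfused (brain ischemia). Per the labels, RNA was extracted with Trizol and libraries for messenger RNA were made from 1 ug of total RNA with an MGIEasy kit. Reads were aligned with STAR 2.7.3a to the susScr11 build and counted per gene with featureCounts 2.0.1, according to the submitters' processing notes. The strand setting, the annotation file and the normalization tool are not given in the sources used here.

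The deposited table held a normalized expression signal for 24999 genes in 19 columns, all of which were mapped to a sample. Each value was a read count that the authors had divided by one size factor per library. This was tested on the values: within every column 100% of the values were whole multiples of a single step, with a tolerance of 0.01 reads and a largest distance of 0.0012 reads. The size factors matched median-ratio factors computed over all 19 libraries, with ratios of 1.00 in the lowest and highest case. Whole reads were recovered by multiplying by the size factor and served only for library depth and for the count models named further on. In frontal brain-liver library 1 the step lay so close to 1 that an automatic check of whole reads could not decide, although its values met the same tolerance.

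Gene names were those of the table. Of the 24999 identifiers, 16589 were plain symbols, 8070 were LOC identifiers and 26 had the form of a date, and 24707 were found in the RefSeq gene table of the pig assembly, which also gave positions. The human symbol HSPA1A corresponds to HSP70.2 in the pig table.

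The main test used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2 of the normalized value plus 1. Genes with a mean normalized value of at least 10 over the libraries of a fit were tested, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. Brain-liver ischemia was compared with brain ischemia separately in the frontal cortex and in the temporal cortex. The difference between the 2 effects and the difference between the lobes, averaged over the treatments, came from a model of 4 group means fitted to all 19 libraries. Replicate numbers were not treated as animals in these fits because the labels do not say whether libraries come from separate animals. For the same reason p-values measure only the spread between these samples.

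In each comparison 42 gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjustment over the lists and a minimum of 5 measured genes. The lists held markers of brain and blood cell types, of injury and stress responses, and of synaptic and metabolic pathways. They held 623 entries for 600 genes, of which 572 were matched, 13 of them by locus tag and 3 by synonym, and 28 were not. Camera compares a list with the other genes, so a call means that the members ranked apart from the rest. Camera with a correlation estimated from the data and fry, which tests whether the genes of a list move one way on balance, were run beside it. For each list the median log2 fold change is given as its size, and the fits that leave out a library are compared by the mean log2 fold change of the list. A score per library was the mean over the list of log2 values, each centred on the mean of the gene over all libraries, and scores were compared by exact two-sided permutation over all splits of the libraries. The correlation of the effects in the 2 lobes was set against 100 permutations of treatment made separately in each lobe. Reassignment to the numbers in the same way in both lobes, planned for libraries paired by number, was added late, over 126 splits, with brain libraries taken as paired by number too and frontal brain library 6 kept as brain. That brain libraries pair by number did not hold in the data, where 2 of 5 correlated best with their own number and numbers 2, 3 and 4 differed in which library held a transcript. The same reassignment, and lobes swapped within a number for the brain-liver libraries, gave splits that keep the pairing, also added late.

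The comparisons of each lobe, of the difference between lobes and of the regions, the gene lists, the filter, the thresholds and the rule for named genes were chosen before the data were examined. The gene-list tests for the difference between the effects and for the lobes were added afterwards. The rule names up to 10 genes per direction and comparison (5 for the difference between effects) with the largest log2 fold change among called genes with a symbol, a mean of at least 50 and the same sign in every fit leaving out a library. Where too few were called it takes those with the smallest unadjusted p, up to 4 members per described list by the same p, and 10 fixed genes. No gene was called by limma, so all genes named by this rule are given as not passing the test. Some list members that the rule names are not reported.

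Alternatives covered the pseudocount, the filter, the scaling, robust and weighted fits, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and leaving out each library in turn. After the data were seen, covariates for an oligodendrocyte score, the mitochondrial share of reads and Y-linked expression were added, as were fits without the 3 libraries with high pituitary or choroid plexus transcripts and fits of the brain-liver libraries alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

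The fits were tested on simulated data with the group sizes of the study and its spread per gene. Each gene was drawn independently of the others. Of 100 genes changed 2-fold, limma recovered 18 in the frontal comparison, 18 in the temporal comparison, 4 for the difference between effects and 63 for the lobes. Of 100 genes changed 4-fold it recovered 82, 78, 60 and 98. A simulated shift of the mural cell list was called in all 4 comparisons, with 0 of the 41 other lists called. Because the simulated genes did not vary together, this does not show how often real, correlated lists are called without a shift. Other splits of the real frontal libraries called a median of 15 lists.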

Results

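Transcript levels were measured by RNA sequencing in the frontal and temporal cortex of pigs after 30 min of global cerebral ischemia, with or without simultaneous ischemia of the liver. The frontal cortex was represented by 6 libraries after brain ischemia and 4 after brain-liver ischemia, and the temporal cortex by 5 and 4. On average 60404422 reads per library were assigned to genes, with a range of 53360996 to 67679233 (n = 19). The means were 58289567 ± 2905216 reads (SD, n = 6) in frontal brain and 64557488 ± 2336152 (SD, n = 4) in frontal brain-liver libraries. They were 62545795 ± 3860711 (SD, n = 5) in temporal brain and 56746923 ± 2652179 (SD, n = 4) in temporal brain-liver libraries. Depth was higher in the frontal brain-liver than in the frontal brain libraries by exact two-sided permutation (p = 0.00952), which did not pass over 6 library tests (Benjamini-Hochberg adjusted p = 0.0571). In the temporal cortex the exact two-sided permutation p was 0.0635 (adjusted p = 0.191). Mitochondrial transcripts took between 16.2% and 47.0% of the reads of a library. The exact two-sided permutation p for this share was 0.324 between the frontal and 0.476 between the temporal groups.

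The first comparison asked how the frontal cortex differs when the liver is ischemic at the same time as the brain. Genes of mural cells, the smooth muscle cells and pericytes of vessel walls, were called lower after brain-liver ischemia as a list with the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.784), and no member passed over all genes. ACTA2, the actin of smooth muscle, averaged 1585 ± 682 normalized counts (SD, n = 4) after brain-liver ischemia and 3844 ± 1336 (SD, n = 6) after brain ischemia. CNN1, the actin-binding protein calponin of smooth muscle, averaged 823 ± 302 (SD, n = 4) and 1626 ± 379 (SD, n = 6). NOTCH3, a receptor that maintains vascular smooth muscle, had a log2 fold change of -0.91 ± 0.28 (SE), and MYH11, smooth muscle myosin, of -1.19 ± 0.44 (SE). ACTA2 lies on chromosome 14 from 100868145 to 100886732 and CNN1 on chromosome 2 from 70183370 to 70190756 of the pig assembly (Sscrofa11.1).

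Of the 10 measured mural cell genes, 9 had a negative and 1 a positive log2 fold change, with a median of -0.76. The list was called lower (Benjamini-Hochberg adjusted p = 9.16e-05, limma camera). With an estimated correlation the unadjusted p was 0.0187 and no list was called (smallest adjusted p = 0.784). None of the 10 genes passed the adjustment over all genes, and 4 passed when adjusted over the list alone. The score per library was lower after brain-liver ischemia by exact permutation (two-sided p = 0.0333, over 210 splits). This did not pass over the 42 lists (adjusted p = 0.995). Endothelial markers had a median of -0.26 (13 of 13 below 0, adjusted p = 0.077, not called). Fibroblast and meningeal markers had a median of -0.63 (10 of 10 below 0, adjusted p = 0.0146). The mural call was kept in all 10 fits that left out a library, with list means from -0.82 to -0.33 around -0.60 over all libraries. The smallest mean, -0.33 with an adjusted p = 0.0294, was found without frontal brain-liver library 4, which had the lowest score. The highest frontal values of ACTA2 (6153) and CNN1 (2213) were in frontal brain library 6, which had pituitary transcripts. Temporal brain library 5, which had them too, held the highest values of all (12362 and 3215).

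**Figure D1:**
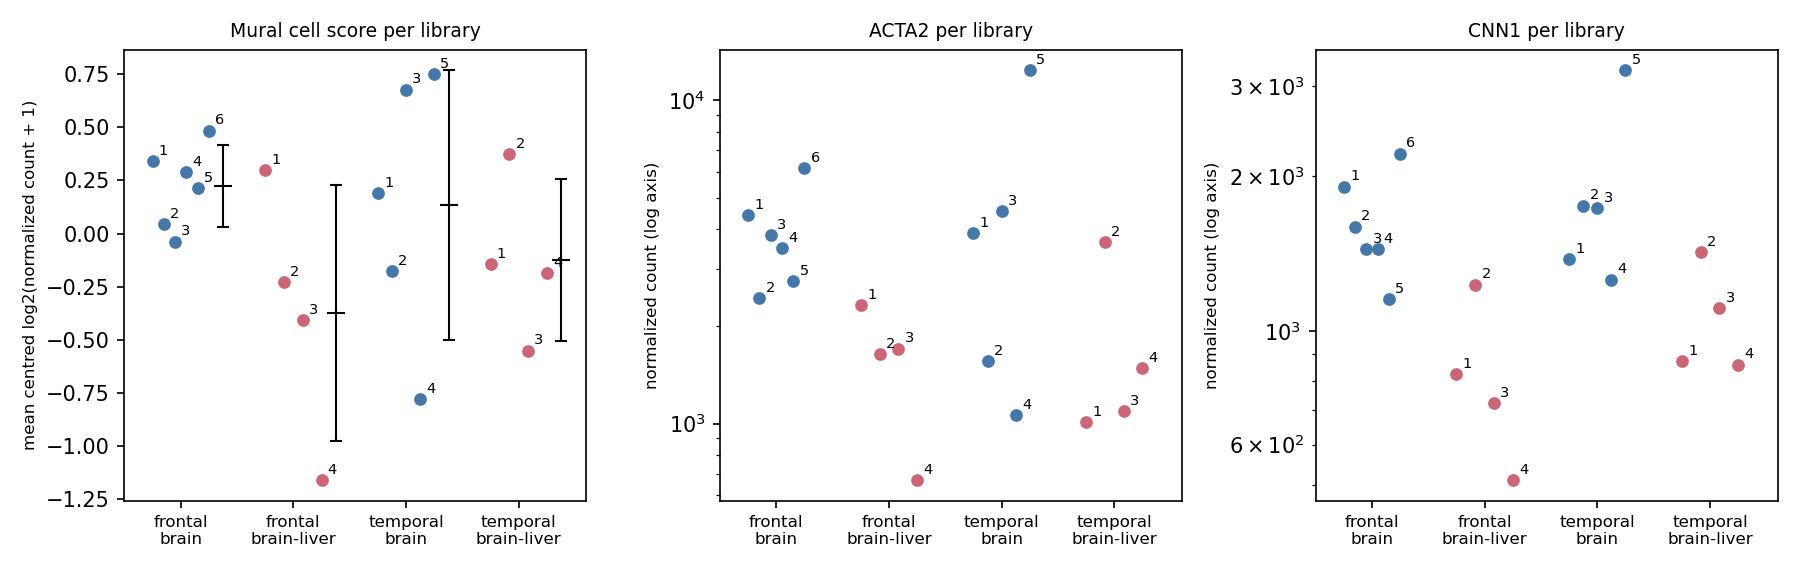
Mural cell score (mean centred log2 of the normalized count plus 1) and normalized counts of ACTA2 and CNN1 (log axes) in each of the 19 libraries, numbered by replicate, with blue for brain and red for brain-liver ischemia. Bars beside the scores give the mean and SD of each group; frontal brain-liver library 4 has the lowest score, -1.16.

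In all, 10 of the 42 lists were called in the frontal cortex with the preset correlation, 8 of them lower. Of the neuronal lists, 3 were called lower, and each call was lost with an estimated correlation (adjusted p = 0.976). Inhibitory neurons (median -0.03, mean 0.42, 6 of 12 above 0, adjusted p = 0.337), glutamate receptors (adjusted p = 0.183), GABA receptors (adjusted p = 0.499) and voltage-gated channels (adjusted p = 0.337) were not called. The synaptic vesicle release genes, which load and fuse transmitter vesicles, had a median log2 fold change of -0.28, with 17 of 20 members below 0 (adjusted p = 0.000489). The syntaxin STX1A averaged 3733 ± 1358 normalized counts (SD, n = 4) against 6334 ± 1338 (SD, n = 6), and the complexin CPLX2 had a log2 fold change of -0.61 ± 0.25 (SE). Markers of excitatory neurons had a median of -0.54 (9 of 12 below 0, adjusted p = 0.00911). The vesicular glutamate transporter SLC17A7 was at -0.75 ± 0.29 (SE) and the kinase CAMK2A at -0.88 ± 0.39. The neuronal transcription factors NEUROD2 and NEUROD6 were at -0.75 ± 0.28 and -1.11 ± 0.50. Pan-neuronal markers such as THY1 (-0.49 ± 0.21) and SYN1 (-0.61 ± 0.29) had a median of -0.30, with 9 of 14 below 0 (adjusted p = 0.0365). The unadjusted p with an estimated correlation was 0.229 for synaptic vesicle release, 0.202 for excitatory and 0.404 for pan-neuronal markers. No member of the 3 lists passed when adjusted over the list alone. Without frontal brain-liver library 1 the pan-neuronal mean turned from -0.19 to 0.10, the synaptic vesicle mean went from -0.28 to -0.0070, and both calls were lost. The excitatory call was lost without frontal brain-liver library 1 (-0.19) or 4 (-0.23). The pan-neuronal call was also lost without frontal brain library 1 (-0.11), 2 (-0.15) or 3 (-0.13).

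Glial and metabolic lists were called in both directions with the preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.976 for each). Astrocyte markers had a median of -0.31 (12 of 13 below 0, adjusted p = 0.00753). The glutamate transporter SLC1A2 was at -0.81 ± 0.42 (SE), the growth factor receptor FGFR3 at -0.82 ± 0.42, ALDOC at -0.46 ± 0.29 and SOX9 at -0.31 ± 0.20. Microglial markers had a median of -0.19 (13 of 14 below 0, adjusted p = 0.0202), including the receptor CSF1R (-0.56 ± 0.22) and the fructose transporter SLC2A5 (-0.88 ± 0.35). Glycolytic enzymes had a median of -0.18 (16 of 17 below 0, adjusted p = 0.00828), with -0.43 ± 0.18 for the phosphofructokinase PFKP. Oligodendrocyte markers, the myelin genes, had a median of 0.58 and 13 of 13 members above 0 (adjusted p = 0.0494), with 0.84 ± 0.64 for MOG and 0.92 ± 0.68 for UGT8. MBP, the myelin basic protein transcript, ranged from 64447 to 2018880 normalized counts over the 19 libraries. With an estimated correlation the unadjusted p was 0.178 for astrocytes, 0.317 for microglia, 0.179 for glycolysis, 0.221 for fibroblasts and meninges and 0.46 for oligodendrocytes. In these lists 0 members passed when adjusted over the list alone. Without frontal brain-liver library 4 all 5 of these calls were lost: the means were -0.20 for astrocytes, -0.19 for microglia, -0.08 for glycolysis and -0.27 for fibroblasts, and the oligodendrocyte mean turned from 0.53 to -0.066. The oligodendrocyte call was also lost without frontal brain-liver library 1 (0.30) or frontal brain library 1 (0.36), 4 (0.25) or 6 (0.48). The microglial call was lost without frontal brain-liver library 2 (-0.29) or 3 (-0.26) or frontal brain library 1 (-0.23) or 2 (-0.15). Without frontal brain library 5 the astrocyte (-0.26), glycolysis (-0.17) and fibroblast (-0.48) calls were lost. The fibroblast call was also lost without frontal brain-liver library 2 (-0.46) or frontal brain library 4 (-0.27).

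Interferon response genes, which respond to type I interferon and limit viral replication, were called higher in the frontal cortex after brain-liver ischemia (median log2 fold change 0.79, 21 of 21 above 0, adjusted p = 1.46e-06). The call was lost with an estimated correlation (0.871, adjusted p = 0.976, unadjusted p 0.196). RSAD2, the antiviral enzyme viperin, averaged 3869 ± 4456 normalized counts (SD, n = 4) against 1269 ± 1787 (SD, n = 6). IFIT2, DDX60 and USP18 had log2 fold changes of 1.52 ± 0.80, 1.42 ± 0.80 and 0.89 ± 0.51 (SE). The exact two-sided permutation p of the score was 0.267. None (0) of the members passed when adjusted over the list alone. The scores of frontal brain-liver libraries 1 and 2 were 1.42 and 2.28, above the highest frontal brain library at 1.05. Those of libraries 3 and 4 were -0.43 and -1.11. The call was lost without library 2 (list mean 0.36 against 0.94, adjusted p = 0.0934).

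No single gene passed in the frontal cortex. Limma called 0 of 18769 genes, with 746 at an unadjusted p under 0.05 where chance gives 938. EdgeR called 0 (865 at an unadjusted p under 0.05) and DESeq2 0 (1329, smallest adjusted p = 0.0556). The lower genes with the smallest p were the smooth muscle genes CNN1 and ACTA2, the leiomodin LMOD2 of striated muscle, the integrin ITGA7, the riboflavin transporter SLC52A3, the urea transporter SLC14A1, the synaptic vesicle protein SYNGR3, the kallikrein KLK1, PNLIPRP2 and the receptor GPR35. Their log2 fold changes ran from -1.91 (PNLIPRP2) to -0.76 (GPR35). The higher ones were the ciliary genes TBC1D32 (1.09 ± 0.27, SE) and SCLT1, the synaptic adhesion gene LRRTM2, CDK17, CENPK, EIF5A2, ORC3, SETDB2, IQGAP2 and the DNA repair gene BRCA1. Their log2 fold changes ran from 0.61 (CDK17) to 1.09. Among the fixed genes of injury, the log2 fold change was 0.29 ± 0.83 (SE) for the immediate early gene FOS, -0.41 ± 0.42 for the heat shock gene HSP70.2, 0.34 ± 0.58 for the heme oxygenase HMOX1, 0.45 ± 1.15 for IL1B and 1.37 ± 1.16 for IL6. It was -0.22 ± 0.26 for the astrocyte filament GFAP, 0.14 ± 0.37 for glutamine synthetase GLUL, 0.40 ± 0.33 for the water channel AQP4, -0.15 ± 0.33 for the neuronal nuclear gene RBFOX3 and -0.22 ± 0.53 for the neurotrophin BDNF. FOS, HMOX1, IL1B, GLUL, RBFOX3 and BDNF changed sign in at least 1 fit that left out a library.

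The second comparison asked the same question in the temporal cortex. Interferon response genes were again called higher (median log2 fold change 1.18, 21 of 21 above 0, adjusted p = 9.24e-18). The call was lost with an estimated correlation (adjusted p = 0.887, unadjusted p 0.05). RSAD2 averaged 4840 ± 6187 normalized counts (SD, n = 4) after brain-liver ischemia and 734 ± 409 (SD, n = 5) after brain ischemia. USP18, which removes the ubiquitin-like protein ISG15, had a log2 fold change of 1.29 ± 0.46 (SE), DDX60 of 1.98 ± 0.78 and the interferon-induced GTPase GBP1 of 1.65 ± 0.71. The exact two-sided permutation p of the score was 0.0873 over 126 splits, which did not pass over the lists (adjusted p = 0.937). None (0) of the 21 members passed when adjusted over the list alone. The call was kept in all 9 fits that left out a library, with list means of 0.57 (without brain-liver library 1) to 1.78 around 1.31. Temporal brain-liver libraries 1 and 2 scored 2.96 and 1.08, above the highest temporal brain library at -0.14. Libraries 3 and 4 scored -0.34 and -0.67. Numbers 1 and 2 were also the high ones in the frontal cortex, and same-numbered brain-liver libraries correlated across the lobes (0.512 to 0.761). The temporal call is therefore not an independent repeat of the frontal call. T and B lymphocyte markers had a median of 0.69 in the temporal cortex (9 of 11 above 0, adjusted p = 0.0725, not called) and 0.14 in the frontal cortex. Their scores in brain-liver libraries 1 to 4 were 1.46, 0.75, -0.36 and -1.42 in the temporal and 1.45, 1.15, -0.58 and -1.07 in the frontal cortex. The highest brain library was at 0.11 in the temporal and 0.88 in the frontal cortex. In the frontal cortex the scores of brain-liver libraries 1 to 4 were 1.61, 1.02, -0.82 and -0.78 for monocytes and macrophages (highest brain library 1.26) and 1.52, 1.02, -1.32 and -0.73 for neutrophils (highest brain library 1.75). In the temporal cortex they were 0.31, 0.87, -0.91 and -1.83 for monocytes and macrophages and -0.40, 0.41, -1.32 and -1.08 for neutrophils.

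**Figure D2:**
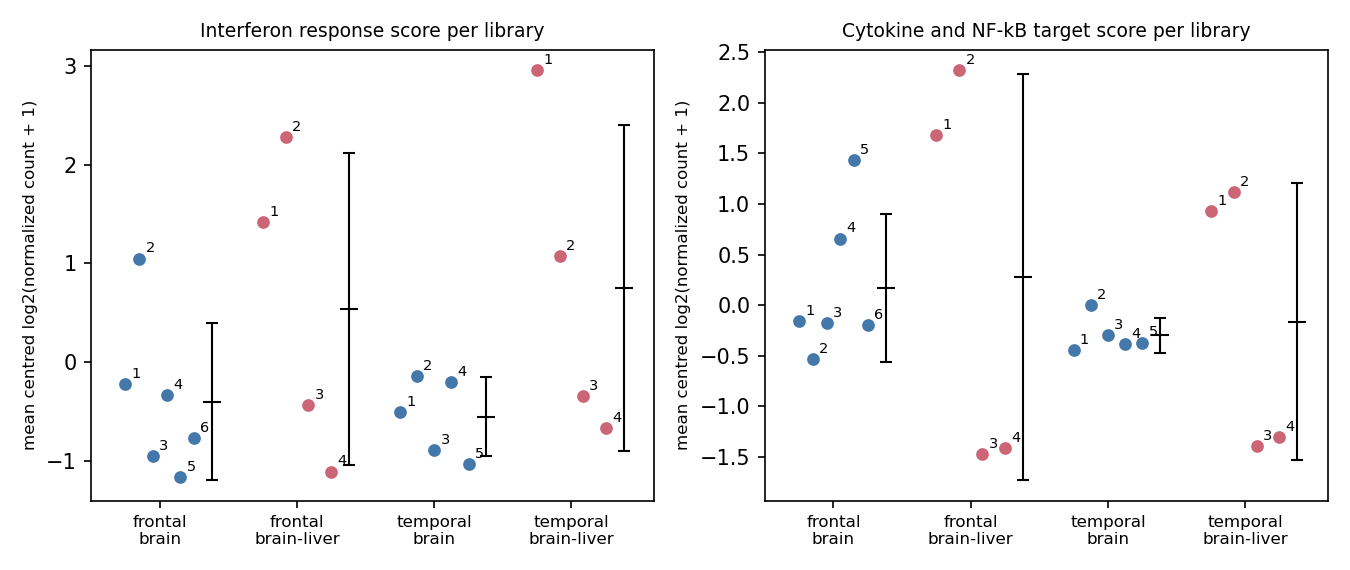
Scores of the interferon response list and of the cytokine and NF-kB target list (mean centred log2 of the normalized count plus 1) in each of the 19 libraries, numbered by replicate, with blue for brain and red for brain-liver ischemia and bars for the mean and SD of each group. Brain-liver libraries 1 and 2 have interferon scores of 1.42 and 2.28 in the frontal cortex and 2.96 and 1.08 in the temporal cortex, and libraries 3 and 4 lie among the brain libraries.

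In the temporal cortex, 3 other lists were called with the preset correlation and lost with an estimated one (adjusted p = 0.887 for each). Cell cycle genes had a median of 0.36 (11 of 14 above 0, adjusted p = 0.0106). The checkpoint kinase BUB1 averaged 55.8 ± 14.0 normalized counts (SD, n = 4) against 25.7 ± 11.6 (SD, n = 5). The replication helicase MCM5 was at 0.57 ± 0.23 (SE), CDK1 at 0.61 ± 0.38 and PCNA at 0.27 ± 0.18. Glutamate receptor and postsynaptic density genes had a median of -0.27 with 17 of 17 members below 0 (adjusted p = 0.0125). The NMDA receptor subunit GRIN2B was at -0.64 ± 0.28, with GRIA3 at -0.37 ± 0.30, SHANK3 at -0.29 ± 0.24 and DLG4 at -0.38 ± 0.33. Neutrophil markers had a median of -0.46 (10 of 11 below 0, adjusted p = 0.0168). ALOX5AP, the activator of leukotriene synthesis, was at -0.85 ± 0.27, with PGLYRP1 at -0.57 ± 0.40, MMP8 at -1.54 ± 1.15 and CSF3R at -0.53 ± 0.44. With an estimated correlation the unadjusted p was 0.0793, 0.284 and 0.192 in this order. None (0) of the members passed when adjusted over the list alone. Without temporal brain-liver library 1 the cell cycle (0.16) and glutamate (-0.14) calls were lost, and without library 4 the glutamate (-0.13) and neutrophil (-0.34) calls. The neutrophil call was also lost without temporal brain-liver library 3 (-0.26) or brain library 3 (-0.39) or 5 (-0.23). The cell cycle call was also lost without brain-liver library 2 (0.26) or brain library 5 (0.24), and the glutamate call without brain library 1 (-0.23), 3 (-0.21) or 4 (-0.17). Apart from interferon response, lists called in the frontal cortex were not called here but had medians of the same sign. These were -0.32 for mural cells (adjusted p = 0.127), -0.34 for microglia (0.104) and 0.30 for oligodendrocytes (0.248). They were -0.28 for fibroblasts, -0.10 for astrocytes, -0.08 for glycolysis, -0.16 for excitatory neurons, -0.12 for synaptic vesicle release and -0.05 for pan-neuronal markers.

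No single gene passed in the temporal cortex. Limma called 0 of 18719 genes, with 378 at an unadjusted p under 0.05 where chance gives 936. EdgeR called 0 (576 at an unadjusted p under 0.05) and DESeq2 0 (869, smallest adjusted p = 0.0748). ETV5, a transcription factor of growth factor signalling, averaged 7202 ± 1322 normalized counts (SD, n = 4) after brain-liver ischemia and 12664 ± 1564 (SD, n = 5) after brain ischemia. It lies on chromosome 13 from 123873346 to 123930292. The other lower genes named by the rule were GATA2, SEMA3G, SAMD14, FMO1, TBKBP1, the oxygen-binding neuroglobin NGB, NAALAD2, DDAH1 and BST1. Their log2 fold changes ran from -2.06 (FMO1) to -0.54 (TBKBP1). The higher ones were the retinoic acid enzyme ALDH1A1 (1.71 ± 0.45, SE), KIF6, SEMA7A, the cytotoxic granule gene NKG7, TBC1D32, the sheddase ADAM17, PVRIG, the acid sphingomyelinase SMPD1, PARP3 and MYH14. Their log2 fold changes ran from 0.52 (ADAM17 and MYH14) to 1.71. Among the fixed genes, the log2 fold change was 0.25 ± 0.59 (SE) for FOS, -0.16 ± 0.51 for HSP70.2, 0.60 ± 0.51 for HMOX1, 0.30 ± 0.99 for IL1B and 0.04 ± 0.83 for IL6. It was 0.13 ± 0.33 for GFAP, 0.25 ± 0.37 for GLUL, 0.68 ± 0.40 for AQP4, -0.04 ± 0.43 for RBFOX3 and -0.43 ± 0.66 for BDNF. FOS, HSP70.2, IL1B, IL6, GLUL, RBFOX3 and GFAP changed sign in at least 1 fit that left out a library.

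The effects of liver ischemia in the 2 lobes were compared directly. No gene passed: limma called 0 of 18791 genes (31 at an unadjusted p under 0.05 where chance gives 940), edgeR 0 (100) and DESeq2 0 (163). This limma fit took the lobes as independent, although the brain-liver libraries paired across them by number. Its 31 lay below the count of every other split that ignored this pairing (median 693, lowest 57). In splits that kept it, with brain libraries taken as paired too, the others had a median of 209 and a lowest count of 22. Of these 100 splits, 99 gave at least 31, the actual one included. With the replicate number as a fixed block the count was 174, and as a random effect 152, again with 0 genes called. The 0 calls therefore do not show that the effects are equal. The genes with the smallest p were ITGA7, an integrin of muscle cells with a difference of 0.83 ± 0.30 (SE), RAPSN, MELTF, ELMO2 and the fructose-bisphosphatase FBP2, with a more positive effect in the temporal cortex. On the other side they were LHFPL3 (-0.72 ± 0.31), the cyclin CCNE2, the phosphate exporter XPR1, the arginase ARG2 and ARHGAP36. Across 18490 genes the log2 fold changes of the 2 lobes were correlated (Pearson r = 0.622, Spearman rho = 0.617, 74.3% with the same sign). In 100 permutations of the treatment within each lobe the highest Pearson r was 0.551 and the median -0.0023. These permutations ignored the pairing of the brain-liver libraries by number across the lobes (correlation 0.512 to 0.761), so they do not give the r of lobes that share animals without a treatment effect. With treatment reassigned to the numbers in the same way in both lobes, the median r over 126 splits was 0.414. Of these, 9 splits, the actual one included, gave an r as large (exact one-sided permutation p = 0.0714). The correlation therefore did not pass this test. These splits also took brain libraries as paired by number, which did not hold in the data. They therefore give the r of lobes that share animals only in part. Genes are not independent replicates. Leaving out a library gave 0.418 (without frontal brain-liver library 1) to 0.656. Of the covariance of 0.0889 between the effects, 0.0845 (95.1%) was estimated to come from brain-liver libraries with the same number in both lobes, and the highest covariance in the permutations was 0.15.

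In tests of this difference, 10 lists were called with the preset correlation, 8 with a more positive effect in the temporal cortex. All 10 calls were lost with an estimated correlation (smallest adjusted p = 0.936). Their median differences in log2 fold change were 0.57 for T and B lymphocytes (CD79A 0.57, CD4 0.90, CD2 0.96, CD3D 1.09), 0.41 for reactive astrocytes (SPHK1 0.81, GFAP 0.35, TNC 0.82, CHI3L1 0.56). They were 0.37 for fibroblasts and meninges (SLC22A6 0.64, PTGDS 0.37, FMOD 0.37, LUM 0.43) and 0.36 for interferon response (GBP1 0.86, IRF9 0.29, MX2 0.61). The medians were 0.27 for astrocytes (FGFR3 0.78, SLC1A2 0.46), and 0.27 for mural cells (NOTCH3 0.58, HIGD1B 0.50, MYH11 0.85, CNN1 0.27). Those of synaptic vesicle release (CPLX2 0.59, STX1A 0.66, SYN1 0.37, SNAP25 0.37) and glycolysis were 0.21 and 0.09 (PFKP 0.30, PGAM1 0.22, TPI1 0.24, LDHB 0.20). The 2 lists on the other side were inhibitory neurons, with a median of -0.51 (DLX5 -1.78, GAD1 -1.35, CALB2 -0.93), and oligodendrocyte precursors, with -0.32 (VCAN -1.03, PDGFRA -0.74, SOX6 -0.32, GPR17 -0.55). No SE is given for these members, none of which passed. GAD1, which makes the transmitter GABA, averaged 9139 ± 10237 normalized counts (SD, n = 4) in frontal brain-liver libraries and 2571 ± 942 (SD, n = 6) in frontal brain libraries. Its highest frontal brain-liver value, 24342, was in library 4, which also had the highest inhibitory neuron score (0.96). Adjusted p-values lay between 0.00698 and 0.0256 with the preset correlation. The unadjusted p with an estimated correlation ran from 0.0597 for oligodendrocyte precursors to 0.397 for interferon response. No member passed when adjusted over the list alone. A fit that left out a library kept between 1 and 10 of the 10 calls, with 1 kept without frontal brain-liver library 4. Inhibitory neurons (mean -0.48) kept the call in 10 of 19 fits and lost it without frontal brain-liver library 2 (-0.48), 4 (-0.26), frontal brain library 6 (-0.34), temporal brain-liver library 1 (-0.37), 4 (-0.22) or temporal brain library 1 (-0.44), 2 (-0.43), 3 (-0.39), 4 (-0.40). Oligodendrocyte precursors (mean -0.43) kept the call in 18 of 19 fits and lost it without frontal brain-liver library 4 (-0.17). T and B lymphocytes (mean 0.54) kept the call in 13 of 19 fits and lost it without frontal brain-liver library 3 (0.27), 4 (0.10), temporal brain-liver library 1 (0.090), 2 (0.33) or temporal brain library 4 (0.33), 5 (0.40). Reactive astrocytes (mean 0.43) kept the call in 12 of 19 fits and lost it without frontal brain-liver library 3 (0.18), 4 (0.046), frontal brain library 4 (0.23), 5 (0.22), temporal brain-liver library 1 (0.22), 2 (0.26) or temporal brain library 1 (0.23). Fibroblasts and meninges (mean 0.34) kept the call in 10 of 19 fits and lost it without frontal brain-liver library 2 (0.24), 4 (0.048), frontal brain library 4 (0.049), 5 (0.25), temporal brain-liver library 1 (0.31), 2 (0.097) or temporal brain library 1 (0.37), 2 (0.27), 4 (0.15). Interferon response (mean 0.37) kept the call in 13 of 19 fits and lost it without frontal brain-liver library 3 (0.045), 4 (-0.18), frontal brain library 2 (0.079), temporal brain-liver library 1 (-0.36), 2 (0.26) or temporal brain library 5 (0.25). Astrocytes (mean 0.26) kept the call in 12 of 19 fits and lost it without frontal brain-liver library 1 (0.20), 4 (0.13), frontal brain library 4 (0.19), 5 (0.18), 6 (0.20), temporal brain-liver library 2 (0.15) or temporal brain library 1 (0.11). Mural cells (mean 0.34) kept the call in 15 of 19 fits and lost it without frontal brain-liver library 4 (0.075), temporal brain-liver library 2 (0.17) or temporal brain library 2 (0.26), 4 (0.11). Synaptic vesicle release (mean 0.18) kept the call in 14 of 19 fits and lost it without frontal brain-liver library 1 (-0.092), frontal brain library 1 (0.10), temporal brain-liver library 2 (0.14), 3 (0.023) or temporal brain library 5 (-0.12). Glycolysis (mean 0.12) kept the call in 12 of 19 fits and lost it without frontal brain-liver library 4 (-0.00052), frontal brain library 5 (0.089), temporal brain-liver library 2 (0.052), 3 (0.086) or temporal brain library 1 (0.10), 3 (0.095), 5 (0.043).

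The lobes themselves were compared across both treatments. NECAB2, a neuronal calcium-binding protein on chromosome 6 (4598752 to 4641450), was higher in the temporal cortex. It averaged 2879 ± 940 normalized counts (SD, n = 5) in temporal and 1132 ± 295 (SD, n = 6) in frontal brain libraries. After brain-liver ischemia it averaged 1822 ± 1003 and 855 ± 107 (SD, n = 4 each). RGS16, a regulator of G protein signalling on chromosome 9 (123913179 to 123919119), was lower in the temporal cortex. Its means were 241 ± 61.2 and 385 ± 90.7 after brain ischemia and 225 ± 45.5 and 493 ± 152 after brain-liver ischemia. Neither was called by limma (adjusted p = 0.44 and 0.819). DESeq2 called both, with log2 fold changes of 1.22 (adjusted p = 0.000563) and -0.90 (adjusted p = 0.00502). The highest NECAB2 values were in temporal brain libraries 4 (4134) and 1 (3507) and temporal brain-liver library 4 (3194). The last also had the highest TTR value, 13057. The smallest adjusted p over all genes in limma was 0.999 without temporal brain-liver library 4 and 0.0865 without temporal brain-liver library 3. Fits without any other single library lay between these. The numbers paired the brain-liver libraries across the lobes (correlation 0.512 to 0.761) but not all brain libraries. With the replicate block as a random effect limma called NECAB2 (1.15, adjusted p = 0.0181) and LOC106509501 (1.47, adjusted p = 0.0364). With a fixed replicate block it called 0 genes (2467 at an unadjusted p under 0.05, smallest adjusted p = 0.0774). In the brain-liver libraries alone, whose numbers do pair, the replicate block called 0 genes (776 at an unadjusted p under 0.05, smallest adjusted p = 0.946). On simulated data DESeq2 called 53 unchanged genes in this comparison and limma 11. Limma called 0 of 18791 genes (660 at an unadjusted p under 0.05, chance 940), edgeR 0 (1012) and DESeq2 7. The other 5 called by DESeq2, named after their values were seen, were LOC110260022 (6.11), LOC100739218 (1.85), LOC106509501 (1.56), the cytokine IL11 (-2.86) and the cell cycle gene CDCA7 (-2.18). Further genes with small p in limma were FAM107A, TST, the cortical patterning factor NR2F1 (0.68 ± 0.17, SE), PHYHD1, TBX5, MYOZ1, CCDC146, PPP1R17 and LIMK2, higher in the temporal cortex. Those lower there were BDKRB2, CDC42EP3, HDAC2, UBASH3B, the scavenger receptor MSR1 (-1.50 ± 0.45), DPY19L1, NUP54, PCSK5 and the neurotrophic factor GDNF (-1.09 ± 0.33).

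**Figure D3:**
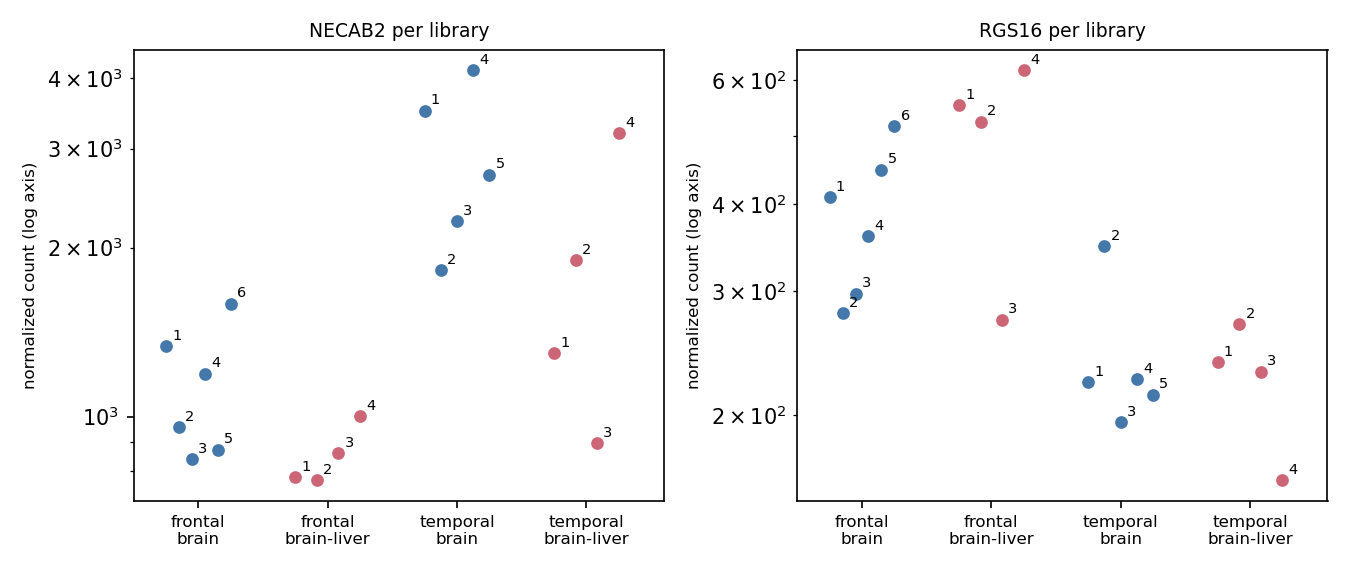
Normalized counts (log axes) of NECAB2 and RGS16 in each of the 19 libraries, numbered by replicate, with blue for brain and red for brain-liver ischemia. NECAB2 averages 1132 in frontal and 2879 in temporal brain libraries, and RGS16 averages 385 and 241.

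Between the lobes, 11 lists were called with the preset correlation. All 11 calls were lost with an estimated correlation (smallest adjusted p = 0.869), and no member passed when adjusted over its list alone. Cell cycle genes were called lower in the temporal cortex (median -0.65, 14 of 14 below 0, adjusted p = 3.43e-07). The log2 fold change was -1.37 ± 0.49 (SE) for the topoisomerase TOP2A, -0.56 ± 0.20 for PCNA, -0.93 ± 0.37 for CDK1 and -0.99 ± 0.40 for TYMS. Monocyte and macrophage markers (median -0.75, 11 of 11 below 0, adjusted p = 0.00174; MRC1 -1.17 ± 0.57, CCR2 -1.36 ± 0.78, F13A1 -0.75 ± 0.43, MS4A7 -0.86 ± 0.51) were lower too. Immediate early genes of neuronal activity were also lower (-0.39, 15 of 17 below 0, adjusted p = 0.00443; NPAS4 -1.47 ± 0.66, FOSL2 -0.41 ± 0.20, EGR3 -0.54 ± 0.30, FOSB -0.96 ± 0.56). Astrocyte markers were higher (0.24, 13 of 13 above 0, adjusted p = 8.86e-05; ALDOC 0.50 ± 0.19, S100B 0.46 ± 0.20, GFAP 0.41 ± 0.20, SLC1A2 0.46 ± 0.28). Nuclear genes of oxidative phosphorylation were higher (0.14, 19 of 21 above 0, adjusted p = 0.00177; NDUFS3 0.24 ± 0.12, NDUFA13 0.21 ± 0.13, NDUFV1 0.17 ± 0.11, SDHA 0.16 ± 0.11), as were oligodendrocyte precursor markers (0.17, 7 of 8 above 0, adjusted p = 0.0259; OLIG1 0.54 ± 0.21, OLIG2 0.51 ± 0.20). With an estimated correlation the unadjusted p was 0.0428 for cell cycle, 0.0522 for astrocytes, 0.124 for monocytes and macrophages, 0.255 for oxidative phosphorylation, 0.205 for immediate early genes and 0.137 for oligodendrocyte precursors. The calls for cell cycle, astrocytes and monocytes and macrophages were kept, with the preset correlation, in all 19 fits that left out a library. The call for oxidative phosphorylation was lost without frontal brain-liver library 3 (0.06) or temporal brain library 2 (0.06), and that for immediate early genes without frontal brain-liver library 1 (-0.28) or 2 (-0.25) or temporal brain-liver library 3 (-0.30). The precursor call was kept in 12 of 19 fits and lost without frontal brain-liver library 1 (0.15), 2 (0.14) or 3 (0.18), frontal brain library 1 (0.15), temporal brain-liver library 2 (0.14) or temporal brain library 1 (0.16) or 3 (0.15).

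The other 5 of the lists called lower in the temporal cortex, and lost with an estimated correlation (adjusted p = 0.869 for each), were reactive astrocytes (median -0.53, 11 of 12 below 0, adjusted p = 0.0259; EMP1 -1.04 ± 0.49 (SE), CD44 -0.99 ± 0.48, S1PR3 -0.55 ± 0.29, but GFAP 0.41 ± 0.20) and neutrophils (-0.59, 10 of 11 below 0, adjusted p = 0.0155; MMP9 -1.40 ± 0.60, CSF3R -0.75 ± 0.39, S100A9 -1.03 ± 0.60, S100A8 -0.90 ± 0.63). Cytokines and NF-kB targets were lower as well (-0.39, 19 of 21 below 0, adjusted p = 0.0259; CCL5 -0.84 ± 0.46, IL6 -1.14 ± 0.78, IL4R -0.61 ± 0.44, CCL4 -1.10 ± 0.83). Microglial markers were lower (-0.31, 14 of 14 below 0, adjusted p = 0.042; TYROBP -0.47 ± 0.32, TREM2 -0.59 ± 0.49, ITGAM -0.37 ± 0.34), as were endothelial markers (-0.26, 11 of 13 below 0, adjusted p = 0.0437; TIE1 -0.26 ± 0.19, CDH5 -0.42 ± 0.31, VWF -0.32 ± 0.25, ESAM -0.33 ± 0.28). With an estimated correlation the unadjusted p was 0.295, 0.234, 0.454, 0.402 and 0.306 for these 5 lists, in the order reactive astrocytes, neutrophils, cytokines, microglia and endothelium. None (0) of their members passed when adjusted over the list alone. Reactive astrocytes (mean -0.47) kept the call in 12 of 19 fits and lost it without frontal brain-liver library 1 (-0.31), 2 (-0.31), frontal brain library 4 (-0.36), 5 (-0.36), temporal brain-liver library 3 (-0.35), 4 (-0.39) or temporal brain library 1 (-0.36). Neutrophils (mean -0.60) kept the call in 12 of 19 fits and lost it without frontal brain-liver library 1 (-0.37), 2 (-0.45), frontal brain library 5 (-0.47), 6 (-0.53), temporal brain-liver library 3 (-0.48) or temporal brain library 1 (-0.50), 2 (-0.53). Cytokines and NF-kB targets (mean -0.46) kept the call in 12 of 19 fits and lost it without frontal brain-liver library 1 (-0.22), 2 (-0.12), frontal brain library 4 (-0.41), 5 (-0.33), temporal brain-liver library 3 (-0.25), 4 (-0.26) or temporal brain library 1 (-0.44). Microglia (mean -0.31) kept the call in 11 of 19 fits and lost it without frontal brain-liver library 1 (-0.21), 2 (-0.32), frontal brain library 1 (-0.27), 2 (-0.22), 6 (-0.31), temporal brain-liver library 4 (0.053) or temporal brain library 2 (-0.23), 4 (-0.23). Endothelial cells (mean -0.21) kept the call in 9 of 19 fits and lost it without frontal brain-liver library 1 (-0.079), 2 (-0.20), frontal brain library 2 (-0.20), 5 (-0.14), 6 (-0.19), temporal brain-liver library 1 (-0.20), 3 (-0.15) or temporal brain library 1 (-0.20), 4 (-0.16), 5 (-0.19).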

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

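All tests of explanations in this part, and the split counts, were chosen only after the results were seen. The gene-list tests of the difference between lobes were added after the data were seen, whereas the tests of single libraries followed fixed rules.

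The higher interferon response genes after brain-liver ischemia, in both lobes, were weighed first. The authors' scaling is argued against, since under quantile normalization the list mean kept at least 0.948 of its deposited size. The shift may rest on 2 of the 4 replicate numbers: 4 of 8 brain-liver libraries, those numbered 1 and 2 in each lobe, scored above the highest brain library of their lobe. More lymphocytes in these libraries stay open, with a lymphocyte median of 0.588 of the interferon median in the temporal and 0.178 in the frontal cortex. Lymphocyte scores were also highest in brain-liver libraries 1 and 2 of each lobe (1.45 and 1.15 frontal, 1.46 and 0.75 temporal). An effect of liver ischemia that reaches only some animals also stays open, untested, because the labels give nothing else that sets numbers 1 and 2 apart.

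The lower mural cell markers in the frontal brain-liver libraries were weighed next. A single library may carry the difference: without frontal brain-liver library 4 the list mean was 0.56 of its value (SD of the ratios 0.338), and the call stayed (adjusted p = 0.0294), so this remains open. Less vessel tissue in the sampled cortex remains open too, with an endothelial median of 0.34 of the mural median and a difference of the scores of -0.359 (exact two-sided permutation p = 0.19). Fibroblast and meningeal markers, which this test did not use, had a median of -0.63 against -0.76 for mural cells. Frontal brain-liver library 4 had the lowest score of both lists (-1.06 and -1.16). A share of meningeal tissue was not tested. A higher share of white matter is not excluded either, since with an oligodendrocyte score as covariate the mural mean kept 0.878 of its size and the list its call (adjusted p = 0.000162), but the exact permutation p was 0.0905. The bounds for these 3 tests were changed after their values were seen, to ask for a margin beyond the spread or an exact p under 0.05. The first bounds argued against all 3 explanations. These sources cannot be told apart from an effect of liver ischemia on mural cells with 4 brain-liver libraries.

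The brain libraries do not all pair across the lobes as their numbers say, whereas the brain-liver libraries do. EIF1AY, a Y-linked gene, had at most 2 reads in 4 libraries (frontal and temporal brain-liver 1, frontal brain 4 and temporal brain 3) and 676 to 1664 normalized counts in the other 15, so frontal and temporal brain libraries numbered 3 and 4 do not match. LOC100519871 had 1 read in frontal brain 3 and in temporal brain 2, against 681 in frontal brain 2 and 380 in temporal brain 3, so number 2 does not match by this transcript either. Both brain-liver libraries 2 lacked it too (4 and 3 reads). Low depth is argued against for EIF1AY, since the reads of the 4 libraries lacking it gave an expected EIF1AY count of at least 550. For LOC100519871 this was not tested. An exchange of libraries 3 and 4 in one lobe is argued against, since over genes stable between lobes temporal library 4 correlated at most 0.141 with frontal library 3, against 0.328 with its best partner. That temporal brain libraries 3, 4 and 5 could come from the animals of frontal brain libraries 4, 5 and 6 remains open: over 4 settings at least 2 of the 3 correlated best with the frontal library numbered 1 higher. Other values go with it. Over 18098 genes these libraries correlated best with frontal libraries 4, 5 and 6 (0.484, 0.256 and 0.376). Of 720 assignments, those with this shift, with temporal library 2 set to frontal 2 or 3, ranked 1 and 2 in each setting. Among brain libraries EIF1AY was lacking in frontal 4 and temporal 3, which also goes with the shift. LOC100519871 was lacking in temporal 2 and frontal 3 but not in frontal 2. By this transcript temporal 2 goes with frontal 3 rather than frontal 2. Pairing by number ranked 29 to 54, which argues against it for the brain libraries.

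For the counts of genes, splits of the libraries into groups of the same sizes decide nothing: the real count is 0 in each of the 4 comparisons, so 100 of 100 splits must reach it. The median of the other splits was 0 too, with up to 370 genes for another split of the frontal, 182 of the temporal, 1 for the difference between effects and 454 for the lobes. Chance could not be excluded for the counts of lists. Of 100 splits, 85 gave at least the 10 calls of the frontal cortex (highest other 30), 100 the 4 of the temporal cortex (27), 86 the 10 of the difference between effects (26) and 83 the 11 of the lobes (27). The real counts lay below the medians of the other splits, which were 15, 15, 14 and 15 in this order. The lowest count of another temporal split was 5. These splits ignored the pairing of the brain-liver libraries by number. With that pairing kept, 54 of 100 splits gave at least the 10 calls of the difference between effects (highest other 21, brain libraries taken as paired too) and 56 the 11 of the lobes (22), and no split called a gene. The splits that call many genes point to a structure of the samples, the source of which was not tested. The list calls of other splits may also come from correlation within the lists above the preset 0.01, such as 0.901 estimated for the frontal oligodendrocyte list. With an estimated correlation no split called more than 1 list.

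In the tests of single libraries within a group, 8 of 164 stood apart, where chance gives 8. Their gap to the nearest library, as a share of the range of the group on the log2 scale, was 0.64 for SLC52A3 (frontal brain library 6, highest), 0.831 for MYH14 (temporal brain-liver 2, lowest), 0.882 for FMO1 (temporal brain-liver 4, highest), 0.858 for TBKBP1 (temporal brain-liver 4, highest), 0.894 for HSP70.2 (temporal brain-liver 1, lowest), 0.723 for SEMA7A (temporal brain 2, highest), 0.833 for GATA2 (temporal brain 4, lowest) and 0.806 for BST1 (temporal brain 4, lowest).

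In the test of the difference between the effects of liver ischemia in the 2 lobes, 10 gene lists were called with the preset correlation. None of them was called with an estimated correlation. At least as many calls came from 86 of 100 splits, or 54 of 100 with the pairing kept, so no list was shown to differ between the lobes. The median differences, temporal minus frontal, were -0.51 for inhibitory neurons, 0.27 for astrocytes, -0.32 for oligodendrocyte precursors, 0.27 for mural cells, 0.37 for fibroblasts and meninges, 0.57 for T and B lymphocytes, 0.36 for interferon response, 0.41 for reactive astrocytes, 0.21 for synaptic vesicle release and 0.087 for glycolysis.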

How the results depend on the processing

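Leaving out the libraries with high PRL, GH1 or TTR, the 3 covariates, the brain-liver libraries alone and all alternatives for the lists of the difference between effects and of the lobes were chosen after seeing the data. No gene was called by limma under any alternative in either lobe or for the difference between effects, and 0 genes under each fit leaving out a library. Between the lobes DESeq2 called 7 genes and a replicate block as a random effect 2 (NECAB2 and LOC106509501). No list was called in any of the 4 comparisons with an estimated correlation (0) or by fry (0). The temporal list count of 4 became 9 with the replicate block, 7 with the oligodendrocyte score and 11 with the mitochondrial share as covariate, and 18 without the PRL, GH1 and TTR libraries. With the replicate block the lists numbered 11 in the frontal cortex, 12 for the difference between effects and 10 between the lobes. The numbers pair the libraries across lobes after brain-liver ischemia (correlation 0.512 to 0.761) but not between treatments or throughout brain ischemia. Leaving out a library gave 6 to 16 lists in the frontal cortex, with 6 without brain-liver library 4 and 16 without brain-liver library 3. In the temporal cortex it gave 4 to 17, with 7, 17 and 12 without brain-liver libraries 2, 3 and 4 and 9, 11 and 9 without brain libraries 2, 4 and 5. For the difference between effects it gave 3 to 19, with 19, 18 and 3 without frontal brain-liver libraries 1, 3 and 4, 5 and 18 without temporal brain-liver libraries 2 and 4 and 6 without temporal brain library 1. Between the lobes it gave 5 to 19, with 6, 5 and 19 without frontal brain-liver libraries 1, 2 and 3, 17 and 7 without temporal brain-liver libraries 1 and 3 and 7 without frontal brain library 5 or temporal brain library 1. It gave a correlation of effects of 0.418 to 0.656. Other alternatives gave a correlation of 0.617 to 0.682. The cause was not tested.

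Of the single genes and lists, 3741 values kept direction and side of the threshold under an alternative. Of the others, 100 lost and 3 gained the threshold and 16 reversed. Leaving out a library, 3550 kept both, 142 lost the threshold and 35 reversed. No gene was called by limma in the main fits, so genes could not lose the threshold and their kept values say little about stability. All losses were of list calls. These numbered 10 in the frontal cortex, 4 in the temporal cortex, 10 for the difference between effects and 11 between the lobes. Each of these calls was lost with an estimated correlation and by fry. With array quality weights the log2 fold change was 0.10 for frontal HSP70.2, 0.10 for temporal RBFOX3, 0.015 for ITGAM between lobes, and -0.10, -0.29 and -0.051 for IRF9, MX2 and TNC in the difference between effects. With the oligodendrocyte covariate it was -0.0031 for frontal GLUL, 0.060 for temporal RBFOX3 and -0.049 for temporal IL6, which was -0.032 with the Y-linked covariate. LUM in the difference between effects was -0.042 with edgeR and -0.050 with DESeq2. Without the PRL, GH1 and TTR libraries the difference between effects was -0.053 for SYN1, -0.059 for SNAP25 and -0.074 for synaptic vesicle release. The mean of microglia between lobes was then 0.036. Leaving out a library gave, in the frontal cortex, -0.34 to 1.05 for FOS, -0.14 to 0.91 for HMOX1, -0.61 to 1.81 for IL1B, -0.39 to 0.27 for RBFOX3, -0.58 to 0.17 for BDNF, -0.10 to 0.40 for GLUL, -0.39 to 0.10 for pan-neuronal and -0.066 to 1.10 for oligodendrocyte markers. In the temporal cortex it gave -0.11 to 0.93 for FOS, -0.56 to 0.25 for HSP70.2, -0.54 to 1.13 for IL1B, -0.97 to 0.67 for IL6, -0.038 to 0.51 for GLUL, -0.33 to 0.30 for RBFOX3 and -0.032 to 0.29 for GFAP. For the difference between effects it gave -0.80 to 0.082 for GPR17, -0.11 to 1.13 for LUM, -0.033 to 1.29 for MX2, -0.12 to 0.43 for synaptic vesicle release, -0.36 to 0.95 for interferon response and -0.00052 to 0.19 for glycolysis. Microglia between the lobes ranged from -0.49 to 0.053. The cause was not tested. What limits the calls was not tested by varying depth or spread. On simulated data limma recovered 18 of 100 genes changed 2-fold and 82 of 100 changed 4-fold in the frontal cortex. In the temporal cortex it recovered 18 and 78. The simulated genes were drawn independently, without the structure of the samples that the splits point to. The 0 calls therefore leave many small changes open and do not exclude large ones in genes that vary widely between libraries.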

Other observations

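The values in this part were looked up only after the data were seen, and no explanation was tested on them except where a test is named.

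Gene groups tied to the liver were not called in either lobe. Genes of ammonia, glutamine and water handling in astrocytes had a median log2 fold change of -0.10 in the frontal (adjusted p = 0.457) and 0.14 in the temporal cortex (adjusted p = 0.655), and genes of ketone body and lactate use one of 0.09 and 0.15 (adjusted p = 0.728 and 0.34). Hepatocyte markers, transcripts that encode plasma proteins, had medians of -0.60 and -0.22 (adjusted p = 0.0704 and 0.248). The proteins themselves were not measured. The classical responses to ischemia were not called either: medians were 0.04 and 0.01 for hypoxia genes, 0.02 and 0.03 for heat shock proteins, -0.09 and -0.05 for immediate early genes, 0.12 and 0.11 for cytokines and NF-kB targets and 0.16 and 0.07 for apoptosis genes. Mitochondrially encoded transcripts had medians of -0.42 and -0.26 (adjusted p = 0.0637 and 0.127). In the frontal cortex the median and the mean differed in sign for inhibitory neurons, hypoxia, heat shock, complement and pyroptosis genes, and in the temporal cortex for hypoxia genes. For T and B lymphocytes in the frontal cortex the test ranked the list lower although the median was above 0.

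Scores of cytokines and NF-kB targets in the brain-liver libraries numbered 1 to 4 were 1.68, 2.32, -1.47 and -1.41 in the frontal and 0.93, 1.12, -1.39 and -1.30 in the temporal cortex. TTR, a transcript of the choroid plexus, reached 13057 normalized counts in temporal brain-liver library 4 and at most 1090.1 elsewhere. The pituitary hormone transcripts PRL and GH1 reached 303 and 703 in temporal brain library 5, with 605 for the forebrain factor SIX3, and 49.7 and 31.6 in frontal brain library 6. The highest CXCL10 value, 33472, was in frontal brain-liver library 2, and the highest ISG15 value, 292179, in temporal brain-liver library 1.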
